A study of Homo sapiens with 6 samples.

How the data were processed

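The series measured mRNA of PC3 cells by RNA sequencing in 6 libraries, 3 from cells given a non-specific siRNA and 3 from cells given an siRNA against paxillin, 72 h after transfection. RNA was purified with a Qiagen RNeasy kit and libraries were made with an Illumina TruSeq mRNA kit, per the labels' protocols. Groups and replicate numbers came from the sample titles. The sequences and the number of the siRNAs are not given in the sources used here.

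The first deposited table gives estimated counts of fragments per gene for 23285 genes, 1 column per library, per the file headers. The submitters' processing notes name Cufflinks 2.0.2, FastQC 0.10.1 and the hg19 build, and the table has the layout that Cufflinks writes. The aligner, the annotation and the use of strand are not given in the sources used here. The values showed that each library had been multiplied by 1 factor. A single read was worth 0.842, 0.926 and 1.369 estimated counts in non-specific siRNA replicates 1 to 3 and 0.825, 0.852 and 1.260 in paxillin siRNA replicates 1 to 3. Between 91.2% and 91.7% of the values above 0 were whole multiples of that step within 0.05. Divided by it, the libraries held about 33600000, 30300000 and 22200000 reads with non-specific siRNA and 31100000, 29600000 and 22700000 with paxillin siRNA, so replicate 3 was the shallowest of both groups. The second deposited table gives FPKM per gene and library with confidence bounds, which were not used, per the file headers. FPKM were used in alternatives only. A value of 0 allows up to 3 single reads in a library, which is 0.0892 to 0.135 CPM, and such floors cover counting error only. Coordinates are those of the count table (hg19), with starts raised by 1, because the loci whose length equals that of their gene were 1899 if starts count from 0 and 253 if they count from 1.

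Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood test, group as the only term, two-sided). Adjusted p-values are Benjamini-Hochberg values over the 15876 genes kept, with a threshold of 0.05, unless they are said to be adjusted over the list alone. Group levels are TMM-scaled CPM as mean ± SD (n = 3), given for non-specific and then paxillin siRNA. The SE of a log2 fold change is its size divided by the square root of the test's F. On simulated data with the real means and library sizes, the edgeR step on 15876 genes recovered 65% of genes changed 2-fold and 99% of those changed 4-fold, and 8.89% of its calls were false. With the replicate block it recovered 97% and 100%, with 5.74% false. Changes were planted only in genes with an average log2 CPM above 2, and genes were drawn independently of each other. Each fit was tried on data simulated from its own model and dispersions, so these recoveries do not compare the 2 fits.

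Whether the replicate numbers pair the libraries was checked before the calls of the 2 fits were compared. The deviations of same-numbered libraries from their group means correlated across genes at 0.34, 0.43 and 0.56 for numbers 1, 2 and 3, all above 0.1. Differently numbered libraries of the 2 groups gave -0.48 to 0.11, with non-specific siRNA replicate 2 and paxillin siRNA replicate 1 also above 0.1. Deviations from the mean of 3 libraries depend on each other, so the 3 values are not independent. The labels give the shared replicate numbers, and the library codes in their descriptions also share a number within each pair. They do not say what these numbers stand for, so the pairing was judged by this check. The fit without the block stayed the main one, and the value with the replicate block is printed wherever it changed a call or moved a count of calls by more than 1.5 times.

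The 36 gene lists were written before the data were examined, from textbook knowledge, and all of their 1090 symbols were found in the tables. They cover focal adhesion adaptors and kinases, integrins, collagens and basement membrane, matrix proteases, G1 regulators, DNA replication, mitosis, DNA repair, p53 targets, apoptosis, ERK outputs, growth factors and receptors, YAP and TEAD targets, SRF and MRTF targets, TGF-beta, NF-kB and cytokines, interferon response, epithelial junctions, mesenchymal genes, androgen receptor targets, nuclear receptors, cholesterol, fatty acids, glycolysis and hypoxia, oxidative phosphorylation, ATF4 and the unfolded protein response, heat shock and oxidative stress, ribosomal proteins, lysosome and autophagy, small RNA machinery, and markers of androgen-responsive prostate lines, leukocytes, fibroblasts, endothelium and neuroendocrine cells. *PXN* is in none of them, and some genes are in more than 1 list. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists). Camera with an estimated correlation and fry were run beside it. On simulated data camera called the planted list and 0 of the random lists. The simulated genes were drawn independently of each other, so this could not show false calls that come from correlated genes.

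The rule for named genes was also written before the data were examined. It took *PXN*, then the 10 largest rises and 10 largest falls among genes past the threshold with at least 5 CPM on average in a group, groups that do not overlap and a single named gene that is not a small RNA. It added up to 4 called members of each list with the smallest adjusted p, and the 2 most abundant members of each list called by camera or used as background. It gave 66 genes. Some of these genes and 1 of the lists are not reported here.

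The alternatives were DESeq2 size factors, totals only, no filter on low counts, a filter at 5 CPM, DESeq2 1.42.0, limma-voom, unrounded counts, limma on log2(FPKM + 1) and log2(FPKM + 0.1) over genes with a mean FPKM of at least 1, no FPKM filter, the replicate block, and leaving out each library in turn. Alternatives chosen after the data were seen were counts divided by the value of a single read, leaving out both libraries of a replicate number with and without the block, limma with the block, and the same with a correction for transcript length and GC content. For list tests, the block was also combined with an estimated correlation, with fry and with that correction. Length, GC content and untranslated regions came from GENCODE v29 transcripts (GRCh38), matched by symbol for 86.5% of genes. No coordinates of that build are used. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.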

Results

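RNA sequencing measured the transcripts of PC3 cells, an androgen-receptor-negative prostate cancer line that came from a bone metastasis. The cells had received either a non-specific siRNA or an siRNA against paxillin 72 h earlier. Paxillin, the product of *PXN*, is an adaptor protein of focal adhesions, where integrins link the cytoskeleton to the extracellular matrix. The question was which transcripts differ in these cells when paxillin is reduced. Each group held 3 libraries with replicate numbers 1 to 3, and nothing says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The estimated counts summed to 28310744, 28075986 and 30394729 in non-specific siRNA replicates 1, 2 and 3 and to 25610970, 25252317 and 28651418 in the paxillin siRNA replicates. Log2 CPM values correlated across genes at 0.971 to 0.99 within groups and at 0.954 to 0.986 between them, and genes are not independent replicates. No pair of libraries within a group agreed within sampling noise, the chi-square per degree of freedom being at least 30.8.

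*PXN*, the targeted gene (chromosome 12, 120639094 to 120703574, hg19), was reduced in every library that received its siRNA. Its level was 835, 854 and 718 CPM in non-specific siRNA replicates 1, 2 and 3. In paxillin siRNA replicates 1, 2 and 3 it was 59.2, 55.7 and 91.7 CPM. Between libraries of the same number, 7.09%, 6.52% and 12.8% of the transcript remained, a mean of 8.79% ± 3.45 (SD, n = 3 pairs). The log2 fold change was -3.54 ± 0.24 (SE), with an adjusted p of 0.00613 in edgeR's quasi-likelihood test. An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. *LOC100506649*, which is listed at the same locus, fell as well, from 7.32 ± 1.11 to 1.69 ± 0.191 CPM (SD, n = 3). Reads of the overlapping genes may not be separable, since use of strand is not given in the sources used here. The adjusted p of *PXN* was 0.0819 without non-specific siRNA replicate 1 and 0.0762 without non-specific siRNA replicate 2, at log2 fold changes of -3.52 and -3.50.

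Paxillin siRNA was followed by higher levels of 140 genes and lower levels of 48 among the 15876 genes tested (edgeR, adjusted p under 0.05). Of these 188 genes, 117 were at least 2-fold higher and 28 at least 2-fold lower. With the replicate block, 1858 genes were higher and 1703 lower, and all 188 were among them in the same direction. At least 2-fold changes numbered 540 higher and 341 lower there. Counts of list members called with the block are to be read against the 1858 and 1703 of 15876 genes called there. The 3 libraries of one group lay wholly above or below those of the other for 28.3% of the genes, against 10% by chance. At an unadjusted p under 0.05, 3565 genes passed without the block. The count of calls changed strongly when a single library was left out, while all 188 genes kept their sign each time. Each such fit also had fewer libraries from which to estimate the spread. By edgeR it was 0 without non-specific siRNA replicate 1 or without its replicate 2, where 2633 and 3005 genes had an unadjusted p under 0.05. Without non-specific siRNA replicate 3 the edgeR count was 51 higher and 14 lower. Without paxillin siRNA replicate 1 it was 1 and 1, without replicate 2 of that group 7 and 1, and without its replicate 3 it was 1169 and 1271. DESeq2, run with all 6 libraries only, called 759 genes higher and 800 lower.

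Among the 10 largest rises, *BST2* (chromosome 19, 17513755 to 17516384), which encodes tetherin, a protein that holds enveloped viruses at the cell surface, rose 11.9-fold, from 3.83 ± 1.56 to 45.6 ± 13 CPM (SD, n = 3). Its log2 fold change was 3.57 ± 0.34 (SE; adjusted p = 0.0173). *XAF1*, an interferon-induced gene linked to cell death, rose 11.1-fold to 14.6 ± 5.09 CPM. *RSAD2*, which encodes the antiviral enzyme viperin, rose 9.25-fold to 79.1 ± 49.5 CPM, and *IFI6* rose 8.57-fold to 680 ± 370 CPM. *HSH2D*, an SH2-domain adaptor of blood cells (chromosome 19, 16244838 to 16269377), had the largest rise, 16.9-fold, from 1.13 ± 0.355 to 19.2 ± 13.4 CPM. Its log2 fold change was 4.08 ± 0.61 (SE; adjusted p = 0.0366). *IL23A*, a subunit of interleukin-23, rose 10.6-fold to 18.2 ± 9.98 CPM. *TNFSF10*, which encodes the death ligand TRAIL, rose 6.80-fold to 11.3 ± 2.7 CPM. *EPCAM*, an epithelial adhesion molecule at a locus listed for 2 genes (chromosome 2, 47596287 to 47614167), rose 7.78-fold from 6.76 ± 0.817 to 52.6 ± 27.7 CPM. The lipase gene *LIPH* rose 7.80-fold to 6.54 ± 1.93 CPM. Each of these genes also passed with the replicate block. Limma-voom ended the calls of *HSH2D*, *IL23A* and *EPCAM* (adjusted p = 0.067, 0.0549 and 0.0511), and limma on log2(FPKM + 1) those of the same 3 genes, *RSAD2* and *IFI6*. *XAF1* and *LIPH* did not reach the mean FPKM of 1 asked for there and were not tested. With no FPKM filter limma put them at log2 fold changes of 0.94 and 0.69 against 3.47 and 2.96 (adjusted p = 0.123 and 0.122). On that scale, where the added 1 makes changes of low values smaller, the log2 fold changes were 1.41 for *HSH2D*, 1.95 for *IL23A*, 2.14 for *EPCAM*, 2.05 for *RSAD2*, 1.17 for *TNFSF10* and 2.87 for *BST2*, against 4.08, 3.40, 2.96, 3.21, 2.77 and 3.57, and with 0.1 added *HSH2D* was at 3.05. By edgeR none passed without non-specific siRNA replicate 1 or 2 or without paxillin siRNA replicate 1. *BST2* alone passed without paxillin siRNA replicate 2, where *HSH2D* and *RSAD2* were at log2 fold changes of 3.45 and 2.57 against 4.08 and 3.21. Only *BST2*, *XAF1*, *TNFSF10* and *LIPH* passed without non-specific siRNA replicate 3, and all passed without paxillin siRNA replicate 3.

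Among the 10 largest falls other than *PXN*, *ESM1*, which encodes the secreted proteoglycan endocan (chromosome 5, 54273695 to 54281414), fell 9.10-fold, from 22.5 ± 16.7 to 2.47 ± 0.565 CPM. Its log2 fold change was -3.19 ± 0.56 (SE; adjusted p = 0.048). *FABP4*, a fatty acid binding protein, fell 6.87-fold to 1.88 ± 1.31 CPM. The homeobox gene *GBX2* fell 4.66-fold to 5.19 ± 1.74 CPM, and *PALM3*, a paralemmin, fell 4.75-fold to 1.4 ± 0.447 CPM. *SLC25A43*, a mitochondrial carrier, fell 4.28-fold to 7.2 ± 3.72 CPM. *CALB1*, which encodes the calcium-binding protein calbindin, fell 3.34-fold to 4.74 ± 2.11 CPM. *VPS25*, an ESCRT-II subunit of endosomal sorting, fell 3.22-fold to 9.23 ± 3.04 CPM. *UBE2QL1*, a ubiquitin-conjugating enzyme-like gene, fell 3.19-fold to 10.7 ± 4.72 CPM. *LOC100506649*, described above, fell 4.32-fold. Limma-voom ended the calls of *ESM1* and *GBX2* (adjusted p = 0.0815 and 0.053), and limma on log2(FPKM + 1) those of the same 2 genes, *CALB1* and *UBE2QL1*. The log2 fold changes there were -1.61 for *ESM1*, -1.91 for *FABP4*, -0.99 for *CALB1*, -0.88 for *UBE2QL1*, -1.44 for *SLC25A43* and -1.44 for *LOC100506649*, against -3.19, -2.78, -1.74, -1.67, -2.10 and -2.11. *PALM3* did not reach the mean FPKM of 1 asked for there and was not tested. With no FPKM filter limma put *PALM3* at -0.6 against -2.25 (adjusted p = 0.135). By edgeR none of these falls passed without non-specific siRNA replicate 1 or 2, with *ESM1* at a log2 fold change of -2.44 without the latter, or without paxillin siRNA replicate 1 or 2. Only *ESM1*, *GBX2*, *PALM3* and *LOC100506649* passed without non-specific siRNA replicate 3, and all passed without paxillin siRNA replicate 3, with *FABP4* at -3.52 against -2.78.

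**Figure D1:**
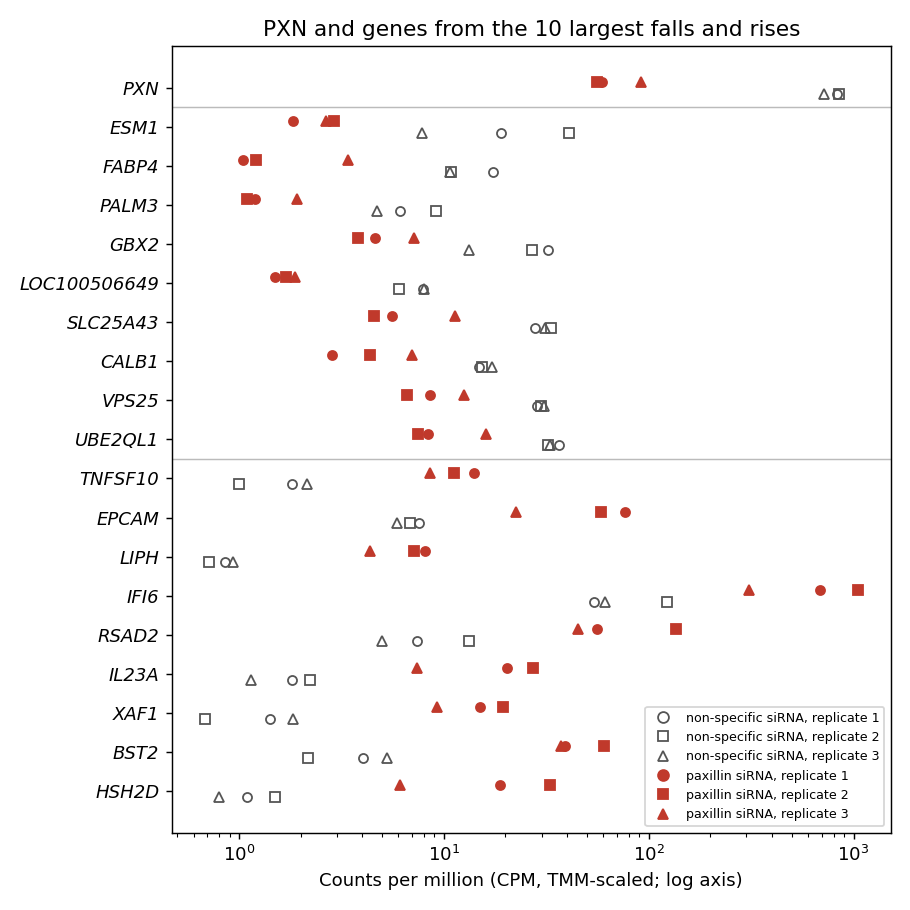
CPM (TMM-scaled counts, log axis) of *PXN* and of the genes named here from the 10 largest falls and the 10 largest rises, in each of the 6 libraries; open grey symbols are non-specific siRNA, filled red symbols paxillin siRNA, and the shape gives the replicate number. The 3 paxillin siRNA libraries lie between 55.7 and 91.7 CPM for *PXN*, all below the non-specific libraries at 718 to 854 CPM. The groups do not overlap for the other genes drawn either, which was a condition for naming them.

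The interferon response genes rose as a group with paxillin siRNA. Of 37 tested members, 23 were higher over all genes tested and 36 adjusted over the list alone, and 36 were higher with the replicate block. None was lower. The median log2 fold change was 2.00, and the pairs of replicates 1, 2 and 3 gave 2.04, 2.11 and 1.74. *PARP9*, at a locus listed for 2 genes (chromosome 3, 122246760 to 122294049), rose 3.55-fold, from 62.8 ± 7.81 to 223 ± 44.4 CPM (SD, n = 3; log2 fold change 1.83 ± 0.18 SE, adjusted p = 0.0173). Its value may hold reads of the other gene there. *IFI44L* rose 6.72-fold to 202 ± 72.1 CPM. *IFITM3* and *IFITM2*, which restrict virus entry and share sequence, so that their reads may be split between them, rose 2.47-fold and 2.35-fold to 622 ± 184 and 574 ± 165 CPM. Camera with a preset inter-gene correlation of 0.01 placed the list above other genes (adjusted p = 3.4e-27). With an estimated correlation the adjusted p was 0.817. The adjustment gave that same value to most of the lists called at the preset correlation, so it does not rank them. The unadjusted p of the interferon list in that camera test was 0.0616, and fry gave 0.00426 unadjusted and 0.145 adjusted. The number of members called was 0 without non-specific siRNA replicate 1, without non-specific siRNA replicate 2 or without paxillin siRNA replicate 1. It was 4 without non-specific siRNA replicate 3, 3 without paxillin siRNA replicate 2 and 36 without paxillin siRNA replicate 3, with *PARP9* and *IFI44L* called in all 3 of these fits and the 2 *IFITM* genes only in the last. On log2(FPKM + 1) limma ended the calls of *IFITM3* and *IFITM2* (adjusted p = 0.0595 and 0.0625) and put *IFI44L* at a log2 fold change of 2.11 against 2.75.

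Cell division genes were lower with paxillin siRNA. All 44 tested mitosis genes were lower adjusted over the list alone and with the replicate block, but only *UBE2C* over all genes tested. *UBE2C*, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell 3.14-fold, from 47.3 ± 13.6 to 15.0 ± 4.52 CPM (SD, n = 3; adjusted p = 0.041; 0.0579 by limma on log2(FPKM + 1)). The proliferation marker *MKI67* stood at 509 ± 92.0 and 241 ± 150 CPM and *BIRC5*, which encodes survivin, at 193 ± 60.8 and 87.8 ± 38.3 CPM. Their adjusted p was 0.164 and 0.107, and 0.00327 and 0.00445 with the replicate block. The median log2 fold change of the mitosis list was -1.08 (camera adjusted p = 2.45e-19; adjusted p = 0.817 with an estimated correlation). Of 49 DNA replication genes, 28 were lower adjusted over the list alone, 0 over all genes tested and 31 with the replicate block, at a median of -0.72 (camera adjusted p = 2.03e-12; adjusted p = 0.817 with an estimated correlation). *MCM7*, a subunit of the replicative helicase, was at 130 ± 41.8 and 80.0 ± 2.9 CPM (adjusted p = 0.117; 0.0122 with the replicate block), a value that may hold reads of the genes at its locus. The polymerase subunit *POLD2* was at 92.5 ± 15.5 and 70.3 ± 6.06 CPM (adjusted p = 0.178). When paxillin siRNA replicate 3 was left out, 40 of the mitosis genes, *MKI67* and *BIRC5* among them (adjusted p = 0.00569 and 0.0108; *MKI67* at a log2 fold change of -1.72 against -1.08), and 20 of the DNA replication genes passed over all genes tested, all lower. Without non-specific siRNA replicate 3 only *UBE2C* passed, and 0 did without any of the other 4 libraries.

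The G1 and DNA repair lists were also placed below other genes by camera. Among 28 G1 cyclins, CDKs and their inhibitors, 1 was lower over all genes, 5 lower and 1 higher adjusted over the list alone, and 10 lower and 2 higher with the replicate block. Their median was -0.32 (camera adjusted p = 0.00197; adjusted p = 0.817 with an estimated correlation). The gene called was *CDKN2C*, which encodes the CDK inhibitor p18, and it fell 1.86-fold to 27.6 ± 5.02 CPM (adjusted p = 0.045; 0.0578 by limma on log2(FPKM + 1)). *CCND1*, cyclin D1, was at 762 ± 153 and 405 ± 125 CPM (adjusted p = 0.101; 0.00827 with the replicate block), and *MYC* at 152 ± 41.0 and 163 ± 61.7 CPM (adjusted p = 0.875). Of 37 DNA repair genes, 0 passed over all genes, 1 was lower adjusted over the list alone, and 15 were lower and 1 higher with the replicate block. Their median was -0.28 (camera adjusted p = 0.000132; adjusted p = 0.817 with an estimated correlation). The checkpoint kinase *ATM* was at 79.7 ± 11.1 and 96.2 ± 6.98 CPM (adjusted p = 0.297), and *PARP1* at 224 ± 49.0 and 190 ± 28.1 CPM (adjusted p = 0.491). Over all genes, 8 G1 genes were lower, *CCND1* among them (adjusted p = 0.0135), 2 were higher and 12 DNA repair genes were lower without paxillin siRNA replicate 3, and 0 of either list passed without any other single library.

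Paxillin siRNA replicate 3 and non-specific siRNA replicate 2 stood apart from their groups in the cell division genes. Over all genes tested, too, paxillin siRNA replicate 3 was no closer to its own group than to the other. Its log2 CPM correlated at 0.973 and 0.971 with paxillin siRNA replicates 1 and 2. With non-specific siRNA replicates 1, 2 and 3 the correlations were 0.978, 0.971 and 0.986. The mitosis list changed by -1.33 and -1.75 log2 units in the pairs of replicates 1 and 2 and by -0.28 in that of replicate 3. The centred level of the list was 0.35, 1.02 and 0.32 in the 3 non-specific siRNA libraries and -1.0, -0.74 and 0.04 in the 3 paxillin siRNA libraries, in replicate order. The DNA replication list was at 0.07, 0.85 and 0.12 and the DNA repair list at 0.06, 0.50 and 0.02 in the non-specific libraries, so replicate 2 was highest there, and at -0.42, -0.48 and -0.08 and at -0.27, -0.22 and -0.04 in the paxillin siRNA libraries. The DNA replication, G1 and DNA repair medians were also nearest to 0 in that pair, at -0.21, -0.11 and -0.06. The *MTRNR2L* family, nuclear genes that closely resemble mitochondrial ribosomal RNA, took 4.93%, 4.09% and 2.32% of the counts in paxillin siRNA replicates 1, 2 and 3. It took 1.42%, 1.60% and 1.11% in the non-specific libraries.

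**Figure D2:**
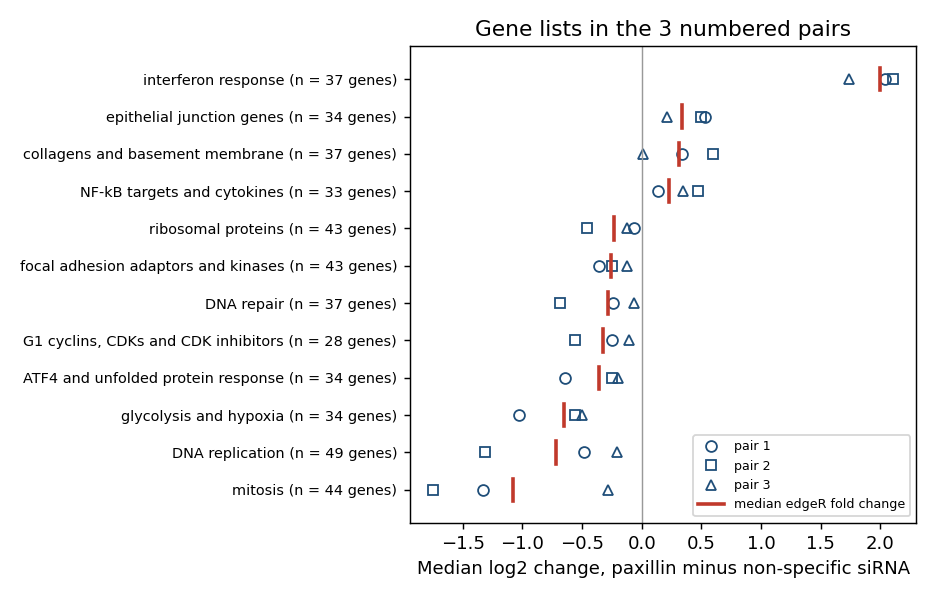
Median log2 change (paxillin minus non-specific siRNA, horizontal axis) of the 12 gene lists that camera called at a preset correlation, for each pair of libraries with the same replicate number (open symbols); red bars mark the median edgeR log2 fold change. The interferon response lies at 1.74 to 2.11 in all 3 pairs, while mitosis lies at -1.33, -1.75 and -0.28; no list kept its call with an estimated correlation.

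The glycolysis and hypoxia, ATF4 and unfolded protein response, and ribosomal protein lists were lower by the list test. By edgeR without the replicate block, no member was called over all genes tested when all 6 libraries were used. Of 34 glycolysis and hypoxia genes, 18 were lower adjusted over the list alone, and 26 were lower and 1 higher with the replicate block. Their median log2 fold change was -0.65, and the pairs gave -1.03, -0.56 and -0.50 (camera adjusted p = 3.53e-08; adjusted p = 0.817 with an estimated correlation). Enolase 1, *ENO1*, was at 2640 ± 423 and 1400 ± 453 CPM, and the pyruvate kinase gene *PKM2* at 2240 ± 459 and 1260 ± 461 CPM (SD, n = 3). Their adjusted p was 0.103 and 0.143, and 0.00428 and 0.00538 with the replicate block. DESeq2 gave 0.00572 and 0.0285. Of 34 ATF4 and unfolded protein response genes, 1 was lower adjusted over the list alone and 13 with the replicate block, at a median of -0.36 (camera adjusted p = 1.11e-05; adjusted p = 0.817 with an estimated correlation). The endoplasmic reticulum chaperones *CALR* and *HSP90B1* were at 1990 ± 184 and 1790 ± 177 CPM and at 1380 ± 241 and 1210 ± 193 CPM (adjusted p = 0.641 and 0.615). Of 43 ribosomal protein genes, 0 passed adjusted over the list alone and 1 was lower with the replicate block, at a median of -0.23 (camera adjusted p = 8.17e-05; adjusted p = 0.832 with an estimated correlation). *RPL8* and *RPLP0* were at 1270 ± 90.3 and 1050 ± 48.1 CPM and at 1340 ± 106 and 995 ± 182 CPM (adjusted p = 0.319 and 0.214), and ribosomal protein genes share sequence with their pseudogenes. The pairs gave -0.64, -0.25 and -0.20 for the ATF4 list and -0.06, -0.46 and -0.12 for the ribosomal list, so replicate 3 was nearest to 0 for the glycolysis and ATF4 lists and not for the ribosomal one. The calls over all genes without paxillin siRNA replicate 3 were 21 glycolysis genes lower, *ENO1* and *PKM2* among them (adjusted p = 0.00993 and 0.0135), and 1 higher, 3 ATF4 genes lower and 1 ribosomal protein gene lower, and 0 passed without any other single library. The *MTRNR2L* share was 2.32% to 4.93% in the paxillin siRNA libraries and 1.11% to 1.60% in the others.

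Epithelial adhesion genes changed in both directions. Of 34 epithelial junction genes, *EPCAM* and *CDH1* were higher and *PKP1* lower over all genes tested, 10 were higher and 1 lower adjusted over the list alone, and 15 were higher and 3 lower with the replicate block. *CDH1*, which encodes E-cadherin, the adhesion molecule of adherens junctions (chromosome 16, 68771195 to 68869444), rose 3.89-fold, from 13.2 ± 6.1 to 51.5 ± 12.6 CPM (SD, n = 3; log2 fold change 1.96 ± 0.36 SE, adjusted p = 0.0496). *PKP1*, a desmosomal plakophilin and the more abundant gene, fell 2.00-fold from 890 ± 32.8 to 446 ± 77.5 CPM (adjusted p = 0.0433). Limma on log2(FPKM + 1) ended both calls (0.0591 and 0.0545), with *CDH1* at a log2 fold change of 1.18. The vesicle protein gene *MAL2* was at 1050 ± 265 and 815 ± 290 CPM (adjusted p = 0.484). The median of the list was 0.34, with 0.53, 0.50 and 0.21 in the pairs (camera adjusted p = 0.00294; adjusted p = 0.817 with an estimated correlation). Of 23 mesenchymal genes, none passed over all genes or adjusted over the list alone, and 2 were higher and 6 lower with the replicate block, at a median of -0.15 (camera adjusted p = 0.202). Over all genes, 14 junction genes were higher and 1 lower and 3 mesenchymal genes lower without paxillin siRNA replicate 3. A single junction gene, neither *EPCAM* nor *CDH1*, was higher without non-specific siRNA replicate 3, and 0 passed without any of the other 4 libraries.

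Of 37 collagen and basement membrane genes, *LAMA4*, a laminin chain, was higher over all genes, at 5.32 ± 0.578 and 10.6 ± 1.05 CPM (SD, n = 3; adjusted p = 0.0453). *LAMA4* did not reach a mean FPKM of 1. Limma on log2(FPKM + 1) with no FPKM filter gave it an adjusted p of 0.254. Adjusted over the list alone, 6 were higher and 1 lower, and 12 were higher and 2 lower with the replicate block. The median was 0.31, with 0.34, 0.60 and 0.01 in the pairs (camera adjusted p = 0.0042; adjusted p = 0.817 with an estimated correlation), and camera gave 0.126 without non-specific siRNA replicate 2. The abundant collagen genes *COL6A1* and *COL6A2* were at 2270 ± 436 and 2630 ± 399 CPM and at 1610 ± 194 and 1830 ± 309 CPM (adjusted p = 0.59 and 0.607). Of 33 NF-kB targets and cytokines, none passed over all genes or adjusted over the list alone, and 10 were higher and 2 lower with the replicate block, at a median of 0.23 (camera adjusted p = 0.0126; adjusted p = 0.817 with an estimated correlation). That call ended without non-specific siRNA replicate 3 (0.154) and without paxillin siRNA replicate 2 (0.236). *ICAM1*, an adhesion receptor for leukocytes, was at 145 ± 34.6 and 249 ± 14.6 CPM and *LIF*, a cytokine, at 282 ± 10.2 and 192 ± 41.9 CPM. Their adjusted p was 0.0771 and 0.129, and 0.00198 and 0.019 with the replicate block. They were 0.046 and 0.0286 without paxillin siRNA replicate 3, where 8 collagen and basement membrane genes were higher and 1 lower and 5 NF-kB targets higher and 2 lower over all genes, while 0 passed without any other single library.

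The focal adhesion list, in which *PXN* itself is not counted, had a median of -0.26 over 43 adaptors and kinases (camera adjusted p = 0.00243; adjusted p = 0.817 with an estimated correlation). None of its members passed over all genes, 5 were lower and 1 higher adjusted over the list alone, and 11 were lower and 3 higher with the replicate block. Filamin A, *FLNA*, was at 1530 ± 99.3 and 1350 ± 186 CPM and vinculin, *VCL*, at 1130 ± 96.3 and 1200 ± 143 CPM (SD, n = 3; adjusted p = 0.578 and 0.799). Of 16 tested integrin genes, 0 passed over all genes and 2 in each direction adjusted over the list alone, against 3 higher and 4 lower with the replicate block (median -0.03, camera adjusted p = 0.867). Of 32 matrix proteases and inhibitors, 1 was lower over all genes, 2 were higher and 1 lower adjusted over the list alone, and 10 were higher and 7 lower with the replicate block (median 0.10, camera adjusted p = 0.863). The smaller change in replicate 3 held for the focal adhesion list too, at -0.36, -0.25 and -0.12 in the pairs. With paxillin siRNA replicate 3 left out, 9 focal adhesion genes were lower and 1 higher over all genes, 2 integrin genes lower and 1 higher, and 6 proteases and inhibitors lower and 4 higher. Without non-specific siRNA replicate 3, 1 protease or inhibitor was lower, and 0 of the 3 lists passed without any of the other 4 libraries.

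Signalling lists showed few calls without the block. Of all genes, 1858 of 15876 were higher and 1703 lower with the block. Without paxillin siRNA replicate 3, 1169 of 16139 were higher and 1271 lower. Counts of called members, here and in the other lists, are to be read against those shares. Of 37 ERK outputs, 1 was lower over all genes, the phosphatase gene *DUSP7*, which fell 1.83-fold to 50.3 ± 7.02 CPM (adjusted p = 0.0404; 0.0545 by limma on log2(FPKM + 1)). Adjusted over the list alone 2 were lower, and 7 with the replicate block (median -0.11, camera adjusted p = 0.054). Of 30 TGF-beta pathway genes, 1 was lower over all genes, 2 were lower adjusted over the list alone, and 5 were higher and 7 lower with the replicate block (median 0.00, mean -0.05, camera adjusted p = 0.831). Among 35 nuclear receptors, *VDR*, the vitamin D receptor, rose 2.87-fold to 34.3 ± 7.12 CPM and *PPARD*, a fatty-acid-sensing receptor, fell 2.16-fold to 44.6 ± 6.18 CPM (adjusted p = 0.041 and 0.0337), and limma on log2(FPKM + 1) put *VDR* at a log2 fold change of 0.82 against 1.52 (adjusted p = 0.0603). The count adjusted over the list alone was 4 higher and 1 lower there, and 5 higher and 4 lower with the replicate block (median -0.05, camera adjusted p = 0.902). *TNFSF10* was the one gene called of 34 apoptosis regulators, with 3 higher and 1 lower adjusted over the list alone and 7 higher and 3 lower with the replicate block (median 0.03, camera adjusted p = 0.867). Of 31 lysosome and autophagy genes, 1 was higher over all genes, 7 were higher adjusted over the list alone, and 7 were higher and 2 lower with the replicate block (median 0.01, camera adjusted p = 0.429). The counts over all genes without paxillin siRNA replicate 3 were 0 higher and 5 lower for ERK, 1 and 4 for TGF-beta, 3 and 3 for nuclear receptors, 5 and 3 for apoptosis and 7 and 1 for lysosome and autophagy. Without non-specific siRNA replicate 3, 1 TGF-beta gene was lower and *TNFSF10* higher, and 0 passed without any of the other 4 libraries.

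No member of the remaining pathway lists passed over all genes tested by edgeR without the replicate block when all 6 libraries were used. Adjusted over the list alone, 3 of 25 SRF and MRTF targets were higher and 3 lower (median -0.20, camera adjusted p = 0.159), 1 of 35 growth factor receptors and ligands was higher (-0.03, 0.881) and 1 of 25 cholesterol genes was higher (-0.02, 0.867). With the replicate block those counts were 4 and 4, 5 and 6, and 3 and 5. None passed adjusted over the list alone among 27 p53 targets (median 0.10, mean -0.01, camera adjusted p = 0.902), 23 YAP and TEAD targets (0.11, mean 0.17, 0.867), 23 androgen receptor targets (0.07, mean 0.02, 0.881) or 28 fatty acid synthesis genes (-0.10, mean -0.04, 0.881). The replicate block called 3 higher and 5 lower, 6 and 3, 4 and 4, and 1 and 4 of these. None passed either among 43 oxidative phosphorylation genes (median -0.05, mean -0.07, camera adjusted p = 0.4), 26 heat shock and oxidative stress genes (-0.11, mean -0.15, 0.129) or 15 small RNA machinery genes (-0.01, mean 0.00, 0.902). The replicate block called 2 lower, 5 lower and 1 higher in them. Leaving out paxillin siRNA replicate 3 made the counts over all genes 1 higher and 8 lower for cholesterol, whose pairs gave -0.30, -0.16 and 0.27, and 1 and 5 for fatty acid synthesis, 2 and 3 for SRF and MRTF, 3 and 3 for growth factors, 1 and 3 for p53, 3 and 1 for YAP and TEAD, 0 and 2 for the androgen receptor, 0 and 2 for oxidative phosphorylation, 0 and 5 for heat shock and 1 and 0 for small RNA genes. None of these lists had a call without any other single library.

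Markers of other cells stayed low or did not pass the edgeR test without the replicate block over all genes when all 6 libraries were used. Of 9 tested markers of androgen-responsive prostate lines, 1 was higher adjusted over the list alone, and 3 were higher and 3 lower with the replicate block (median 0.24, camera adjusted p = 0.85). *HOXB13*, a prostate homeobox gene, was at 692 ± 162 and 470 ± 188 CPM and *TMPRSS2* at 49.0 ± 9.72 and 77.6 ± 5.9 CPM (SD, n = 3; adjusted p = 0.326 and 0.086, and 0.0151 and 0.00315 with the replicate block). Of 12 leukocyte markers, 3 had enough counts to be tested, and 2 of these were higher adjusted over the list alone and with the replicate block. *CD68*, a lysosomal protein of macrophages that many cultured cells express, was at 40.8 ± 7.58 and 66.8 ± 17.4 CPM and *CD14* at 0.835 ± 0.0484 and 1.10 ± 0.256 CPM (adjusted p = 0.116 and 0.448; *CD68* 0.00205 with the replicate block). Of 6 fibroblast markers, none passed without the block and 1 was lower with it (median -0.12, camera adjusted p = 0.863). *COL1A1* was at 69.7 ± 25.6 and 73.9 ± 29.7 CPM and *PDGFRA* at 25.4 ± 6.02 and 14.5 ± 4.62 CPM (adjusted p = 0.906 and 0.137; *PDGFRA* 0.00643 with the replicate block). Of 7 endothelial markers, none passed without the block and 2 were higher with it (median -0.04, mean 0.12, camera adjusted p = 0.867). *KDR* was at 93.0 ± 19.1 and 140 ± 6.23 CPM and *CLDN5* at 26.8 ± 4.26 and 26.1 ± 6.78 CPM (adjusted p = 0.104 and 0.932; *KDR* 0.00624 with the replicate block). Of 3 tested neuroendocrine markers, 1 was lower adjusted over the list alone and with the replicate block, *ENO2*, also a glycolytic enzyme, at 523 ± 97.1 and 306 ± 78.1 CPM (adjusted p = 0.108; 0.00379 with the replicate block). *SYP*, synaptophysin, was at 1.84 ± 0.241 and 1.95 ± 0.161 CPM. *PDGFRA* and *ENO2* were lower over all genes without paxillin siRNA replicate 3 (adjusted p = 0.0381 and 0.0174), as was 1 prostate line marker, and 1 endothelial marker was higher, while 0 markers passed without any other single library.

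In all, camera called 4 of 34 tested lists higher and 8 lower at the preset correlation, with and without the replicate block, and 0 with an estimated correlation, the smallest adjusted p being 0.817 without the block and 0.912 with it and 0 lists having an unadjusted p under 0.05 in either. Fry's directional test called 0 lists without the block, 5 having an unadjusted p under 0.05, and 2 with it, the interferon response and the YAP and TEAD targets (adjusted p = 0.0356 for both). The preset-correlation test called 9 to 14 lists when the 6 libraries were split into 3 and 3 in other ways. Those splits divided the treatments unequally, so part of the treatment difference stayed in them.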

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

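Counts on the scale of a single read, leaving out both libraries of a replicate number, limma with the replicate block, its length and GC correction, and the replicate block combined with an estimated correlation or fry were chosen only after results had been seen. The 188 called genes kept their sign under every alternative in which they had a value. Of 1670 values of named genes under the alternatives, 21 had another sign than in the main result, all of *MYC*, *COL1A1* and *CLDN5* (main log2 fold changes 0.10, 0.08 and -0.04), which passed the threshold in no fit. *MYC* and *COL1A1* were at -0.02 and -0.01 by limma on log2(FPKM + 1), with and without the filter, both at -0.02 at a pseudocount of 0.1, and at -0.12 and -0.08 with the replicate block and without replicate 2. *CLDN5* was at 0.01 with totals only and 0.09 with the block and without replicate 1. Leaving out 1 library or replicate number gave -0.19 to 0.35, -0.28 to 0.41 and -0.27 to 0.09 for the 3 genes. Of 873 values of named genes called at first, 579 stayed past the threshold. Limma-voom ended 6 of 34 such calls, limma on log2(FPKM + 1) 18 of 29, on log2(FPKM + 0.1) 14 of 29 and with no FPKM filter 34 of 34, and the other scalings and filters, DESeq2 and the replicate block 0. Of the named genes not called at first, DESeq2 called 13 and the replicate block 14. Counts of genes depended on the setting far more than directions did. They were 215 higher and 88 lower with no filter on low counts, 759 and 800 with DESeq2, 1858 and 1703 with the replicate block, 1840 and 1725 with limma and the replicate block, and 1691 and 1692 with the length and GC correction added. On the FPKM table limma called 23 higher and 10 lower at a pseudocount of 1 and 46 and 17 at 0.1. With no FPKM filter it called 0 and 0, with 3968 genes at an unadjusted p under 0.05, and *PXN* stood at -3.46 on the log2(FPKM + 1) scale with an adjusted p of 0.0634. The other scalings and filters, limma-voom and unrounded counts moved neither count by more than 1.5 times, and the share of higher genes among calls was 70.8% with DESeq2 size factors and 73.9% with totals only, against 74.5%. Leaving out 1 library gave 0 to 1169 genes higher and 0 to 1271 lower, and *PXN* at -3.81 to -3.41. Without the block, leaving out both libraries of a replicate number gave 0 to 1223 higher and 0 to 1203 lower, and *PXN* at -3.87 to -3.36, its adjusted p being 0.555 (log2 fold change -3.42) without replicate 1. With the replicate block the same gave 282 higher and 173 lower without replicate 1, 683 and 653 without replicate 2 and 2567 and 2318 without replicate 3, and *PXN* passed each time. Over all alternatives the adjusted p of *PXN* ranged from 4.67e-52 to 0.555. The cause of these differences was not tested.

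Of the 34 lists, camera with an estimated correlation called 0 higher and 0 lower, also with the replicate block, and fry called 0 and 0, or 2 higher and 0 lower with the replicate block. Leaving out 1 library left 3 to 4 lists higher and 8 to 10 lower at the preset correlation. The replicate block changed no other call than those printed beside the results. Replicate 3 was sequenced least in both groups. With 3 libraries per group the simulated recovery of 2-fold changes was 65% without the block, for genes with an average log2 CPM above 2. A gene that missed the threshold is therefore not shown to be unchanged.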

Other observations

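The genes in these first paragraphs were chosen after their values were seen. Genes of antigen presentation were higher with paxillin siRNA. *B2M*, the light chain of MHC class I, rose from 855 ± 100 to 2220 ± 364 CPM (SD, n = 3; log2 fold change 1.38 ± 0.19 SE, edgeR adjusted p = 0.0337). *NLRC5*, the transactivator of class I genes, rose from 3.2 ± 0.544 to 13 ± 2.23 CPM (adjusted p = 0.0173). The peptide transporter gene *TAP1* rose from 78.7 ± 19.4 to 194 ± 14.5 CPM, and the immunoproteasome genes *PSMB9* and *PSMB8* rose to 11.4 ± 0.873 and 56.1 ± 1.03 CPM (adjusted p = 0.034, 0.0242 and 0.034). Reads of interferon genes themselves were few. On the scale of single reads, *IFNB1* had 1, 7 and 0 reads in the non-specific libraries and 7, 24 and 6 in the paxillin siRNA libraries. *IL29* had 1, 2 and 0 against 3, 13 and 1, and its relatives *IL28A* and *IL28B* had 2, 2 and 0 against 7, 14 and 1 and 2, 2 and 0 against 3, 13 and 0, so paxillin siRNA replicate 2 held most of the reads of these 4 genes with paxillin siRNA, and *IL28B* had 3 there without it against 4. *IFNA1* had 2, 5 and 0 against 1, 2 and 3 and *IFNA2* 1, 3 and 0 against 3, 2 and 2, while *IFNG* and *IFNK* had 0 in all 6, which allows up to 3 reads in each.

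*TSPAN1*, a tetraspanin, rose from 19.9 ± 5.09 to 103 ± 27.7 CPM, and *TRIM22* and *SAMD9L*, both interferon-induced, rose to 26.4 ± 6.34 and 119 ± 28.6 CPM (adjusted p = 0.0173 for all 3). The hair keratin genes *KRT37* and *KRT38* rose to 35.9 ± 10.7 and 25.7 ± 7.31 CPM from 7.33 ± 3.68 and 5.54 ± 2.82 CPM, with adjusted p of 0.041 and 0.0436, values that are uncertain because the genes share sequence. The nuclear RNA *NEAT1* was at 321 ± 147 and 797 ± 466 CPM (adjusted p = 0.216; 0.000668 with the replicate block). *TGFB1I1*, the closest relative of *PXN*, was at 20.7 ± 1.64 and 10.6 ± 2.51 CPM (adjusted p = 0.0566; 0.00223 with the replicate block). *GAPDH*, often used as a reference gene, was at 2000 ± 177 and 1130 ± 297 CPM, and *HPRT1* at 39.1 ± 6.21 and 21.4 ± 6.64 CPM (adjusted p = 0.0919 and 0.0927; 0.00627 and 0.00375 with the replicate block).

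Among the tests that follow, those of leukocyte RNA, of the siRNA duplex, of untreated cells and of the low 7-mers as a set were chosen after the results were seen, and the test of untreated cells replaced an earlier version whose outcome had been seen.

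The interferon response genes were higher by a median of 2.00 log2 units. Gene length and GC content are argued against, since the median was 2.03 after their trends were removed and 1.98 before (limma with the replicate block). RNA of leukocytes is argued against too, because 1 of 12 markers, *CD68*, reached 5 CPM with paxillin siRNA, and it was at 40.8 CPM without it. A response to the siRNA duplex and one to the loss of paxillin cannot be told apart, as the labels give a single paxillin siRNA treatment and no rescue. The 3 pairs ranked alike by depth of the *PXN* fall and by interferon rise in 3 of 3 cases, which 3 pairs cannot decide.

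Cell cycle genes were lower, much less so in replicate 3. Length and GC content (mitosis median -1.11 after correction and -1.11 before) are argued against as whole causes. Without the 50 most abundant genes the median was -1.08. This decides little about a few abundant genes taking the counts, because the TMM factors already correct for such genes. For replicate 3, removing the largest share of untreated cells that *PXN* allows, 12.8%, moved the mitosis median only to -0.33 (95% bootstrap interval over genes -0.38 to -0.24), and the length and GC correction left it at -0.29. Lower siRNA activity stays open: 12.8% of *PXN* remained against 7.09% and 6.52%, but the summed shift of -0.22 of the 3 strongest 7-mers described below, against -0.32 and -0.34 in pairs 1 and 2, decides nothing, since those 7-mers are not tied to the siRNA and the median log2 change of genes at least 2-fold higher in pair 1 (mean of 10 CPM or more there) was also smaller in pair 3, 0.70 against 1.23 in pair 2. A difference in growth state was not tested.

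An siRNA can also lower transcripts that match its seed in their 3' untranslated region, which was tested as a hypothesis by regressing the blocked log2 fold changes of 12043 genes on the presence of each of 15951 7-mers, with length and base content as terms. The 7-mer with the lowest t was CACACAT (-8.41, 1930 genes, shift -0.113 ± 0.013 SE), which occurs in the coding sequence of *PXN*. ACACACA, which does not occur in the transcript, reached -7.53, so the margin of 2 set beforehand was not met. These 2 7-mers overlap, so their t values are not independent and the margin decides little. AGCCTAA and CCTGAAC, also in the coding sequence, had shifts of -0.101 ± 0.017 and -0.080 ± 0.015. Of 10 7-mers with t below -4, 5 occur in *PXN*, as do 20.1% of those tested. Several of the 10 overlap, such as AGCCTAA and AAGCCTA in *PXN* and ACACACA and CACACAC outside it, so they are not separate matches. Of 4699 transcripts of similar length, 88.9% hold fewer of the 10, below the 95% asked for. Seed-matched silencing therefore cannot be told apart from a chance match to *PXN* without the siRNA sequence, and it may add to the falls in any of the groups above.

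The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In each split other than the real one, the treatments stayed unequally divided. Part of their difference then lay between the groups, and the rest widened the spread within them. The other splits therefore tend to few gene calls and can keep list calls, so they do not show what chance alone gives. The real split gave 188 genes and the highest of the others 0, so 1 of 10 splits gave as many. With the replicate block, of the 4 splits that part all 3 pairs, the real one gave 3561 genes and the highest other 0, so 1 of 4 did. The real split gave 12 lists by camera at the preset correlation and the highest other 14, and 6 of the 10 splits gave at least as many. The number of lists thus does not set the real split apart from the others, which for the reason above decides nothing about chance.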
